A study of Mus musculus with 2 samples.

How the data were processed

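Total RNA from the heart of female B6CASTF1/J mice, a first-generation cross of C57BL/6J and CAST/EiJ, was sequenced by the authors at an age of 18 to 20 months. Per the labels, each library was made from 300 ng of RNA depleted of ribosomal RNA and carried ERCC spike-ins, synthetic RNAs added at known amounts. The labels give 1 group with biological replicates 1 and 2. They name separate biosamples for the 2 libraries but the same donor entry, so whether the libraries came from separate animals was not settled here, and the spread between them may be technical in part.

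For each library 3 tables were used. Per the deposited readme, all of them refer to the mouse genome build mm10 and the GENCODE M21 annotation. The gene table and 1 of the 2 transcript tables were computed by the authors from alignments to the transcriptome, per the deposited readme, and per the file headers they have the column layout of RSEM. The other transcript table was computed by the authors from the read file and an index, per the deposited readme, and per the file headers it has the column layout of kallisto. The programs, their versions and the aligner's settings are not given in the sources used here, so the tables are called the RSEM-layout and the kallisto-layout tables.

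The expected counts deposited in the RSEM-layout tables are estimated reads per gene or transcript, in which a read that fits several genes is split among them; the estimated counts deposited in the kallisto-layout table are of the same kind. The TPM values were deposited by the authors as relative transcript abundances scaled over all rows of a table, spike-ins and mitochondrial genes included, both as the maximum likelihood value and as a posterior mean. The FPKM values were deposited by the authors per kilobase and library size. The isoform percent deposited by the authors is a transcript's share of its gene's TPM. The bounds of a credibility interval were also deposited by the authors, per the file headers, and belong to the posterior TPM, so the maximum likelihood TPM can lie outside them. In the RSEM-layout tables the annotated length exceeded the effective length by 99 nt, while in the kallisto-layout table it did so by 325 nt in replicate 1 and 322 nt in replicate 2.

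The gene table held 55536 Ensembl genes, all of which matched the annotation, 96 ERCC rows, 1 phiX row without counts and 26248 rows with numeric identifiers that held no counts in either library. The kallisto-layout table held transcripts of 55450 of the Ensembl genes, and its transcripts were summed per gene. Expected counts summed to 35897521 in replicate 1 and 36926429 in replicate 2, and estimated counts of the kallisto-layout table to 36103742 and 37044570. At these depths a count of 0 allows up to 3 counts, or 0.0836 and 0.0812 CPM. Intervals and floors cover counting error only, since reads are not independent molecules.

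With 1 group there was no contrast between groups and no test of one. Levels are given as the mean ± SD of TPM over the 2 libraries. Ratios are on the scale of log2(TPM + 0.1), which understates the change of low genes. Before the data were examined, 42 gene lists with 562 different symbols, some of them in several lists, 30 pairs of paralogs, 20 genes for transcript shares, the alternatives and the rule for named genes were fixed. Every list symbol was matched, 2 of them through a newer name, and of symbols with more than 1 identifier the one with the higher mean TPM was used. A list was compared between the libraries by its median log2 ratio, replicate 2 over replicate 1, and by that median's percentile among 10000 random lists of the same size matched on mean expression in 40 bins. The random lists were drawn from nuclear protein-coding genes with any TPM. Noncoding, immunoglobulin and mitochondrial members were thus matched to genes of another class, and mitochondrial mRNAs above their range to the highest bin. The percentile describes these 2 libraries and is not a test of a condition. A paralog pair was called where both libraries lay on the same side of 0 by more than the difference between them.

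Agreement was computed across genes with a mean TPM of 1 or more. The biological coefficient of variation was the square root of edgeR's common dispersion on expected counts rounded to whole numbers, over genes with 10 or more counts in both libraries after TMM scaling, with 50 bootstrap draws over genes for its spread. The calculation was tested on simulated data for the comparison of replicate 2 against replicate 1. Over 15007 genes, coefficients of 0.1, 0.2 and 0.4 were recovered as 0.0995, 0.198 and 0.398. Over 12510 genes, 199 of 200 genes changed 4-fold came out 2-fold or more apart and 2.40% of unchanged genes did so at a coefficient of 0.2. The simulated lists had 12 genes, with ratios drawn independently of each other and with the same spread at every expression level. In the data the spread was wider for genes of low expression, so the matching on expression was not put to the test. Of these lists, 100% of those shifted by 1 on the log2 scale and 5% of unshifted ones fell in the outer 2.5% at either end.

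The rule for named genes takes the 25 nuclear protein-coding genes with the highest mean TPM and the mitochondrial protein-coding genes, up to 4 members of each list with the highest mean TPM, members at 0 in both libraries, both genes of each pair, and the top transcripts of the 20 genes. It also takes the 10 largest positive and 10 largest negative log2 ratios among protein-coding genes with a mean TPM of 5 or more and a mean expected count of 100 or more, Xist, the Y-linked genes, and up to 10 genes that differ most between the tables. A few genes that the rule takes are not reported here by name, though the counts over pairs, lists and genes include them. Genes outside the rule are marked in the text as chosen after their values were seen.

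The alternatives were other detection thresholds, another pseudocount, no filter or a stricter one, posterior mean TPM, FPKM, the kallisto-layout table, TPM rescaled over nuclear protein-coding genes, TMM, DESeq2 size factors or spike-in scaling, protein-coding genes only, and each replicate left out. Work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and with R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0. The CAST/EiJ parent differs in sequence from the reference genome, and the effect of this on the counts was not tested. Alignments and signal tracks named in the deposited readme were not analysed here.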

Results

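Total RNA of the aged female heart was measured in 2 libraries of 1 group, replicates 1 and 2 of female B6CASTF1/J mice at 18 to 20 months. The labels give no treatment or second group, so the data answer which transcripts the heart held, at what level, and how far apart the 2 libraries were. Expected counts totalled 35897521 in replicate 1 and 36926429 in replicate 2. At 1 TPM or more in both libraries, 11990 genes were detected, of which 10991 were protein-coding. All coordinates are those of mm10.

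Mitochondrial RNA and nuclear mRNA made up most of the transcripts in these libraries. The shares are those of RNA depleted of ribosomal RNA and not of all RNA in the heart. Nuclear protein-coding genes held 40.7% ± 0.930 of TPM (SD, n = 2), the 2 mitochondrial rRNAs 18.5% ± 1.31 and the 13 mitochondrial mRNAs 15.4% ± 0.592. The 7SL and 7SK RNAs, small noncoding RNAs of protein targeting and of transcription control, held 13.2% ± 2.34, but 0.00102% in the kallisto-layout table. All genes of the mitochondrial chromosome together held 33.9% ± 1.91 of TPM, but 29.6% ± 1.25 of expected counts, since TPM weights short transcripts more. By expected counts nuclear protein-coding genes held 61.5% ± 0.455 and the 7SL and 7SK RNAs 2.12% ± 0.412.

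**Figure D1:**
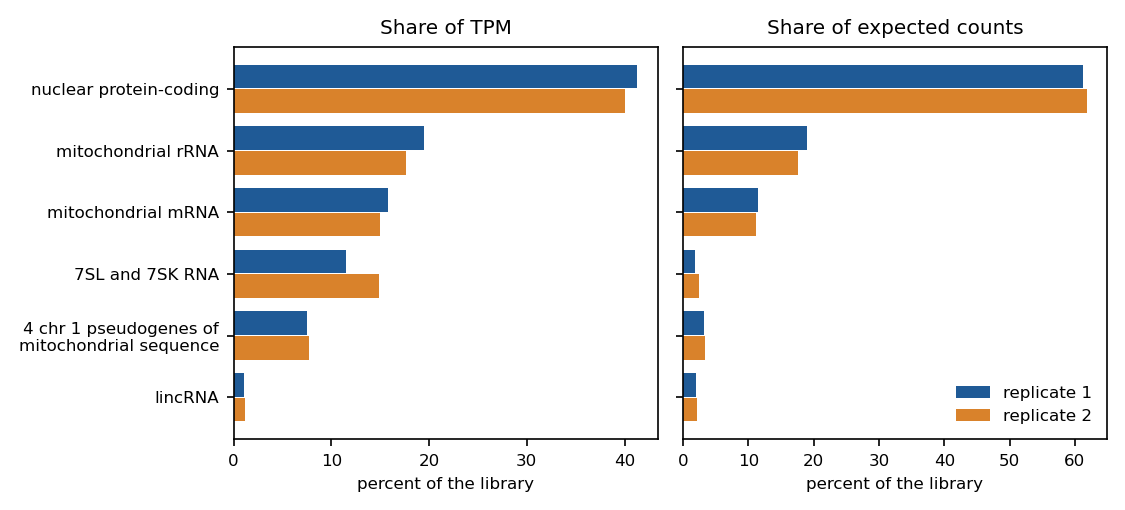
Share of each RNA class in percent of TPM (left) and of expected counts (right), with 1 bar per library. Nuclear protein-coding genes held 40.7% of TPM and 61.5% of expected counts on average, and the 7SL and 7SK RNAs 13.2% and 2.12%, all in the RSEM-layout table.

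Among mitochondrial mRNAs, mt-Co1, a core subunit of cytochrome c oxidase (chromosome M, 5328 to 6872), was the most abundant with 38484 ± 1333 TPM. It was followed by mt-Co3 with 20139 ± 2774 TPM, mt-Atp6 with 19977 ± 1502 TPM and mt-Cytb with 16864 ± 51.2 TPM. In the kallisto-layout table the order differed, with mt-Co1 at 46347 TPM, mt-Atp6 at 34377, mt-Cytb at 19912, mt-Nd1 at 13285 and mt-Co3 at 12193. The complex I mRNAs ranged from mt-Nd6, the one encoded on the minus strand, with 1811 ± 175 TPM, to mt-Nd1 with 12013 ± 68.0 TPM. In the kallisto-layout table mt-Nd4l was lowest of them, with 174 TPM against 9068 ± 37.3 TPM in the RSEM-layout table. mt-Co2 had 478 ± 14.6 TPM in the RSEM-layout table and 2962 TPM in the kallisto-layout table. Of the 31-nt words of mt-Co2, 99.5% also occur in 4 pseudogenes of mitochondrial sequence on chromosome 1, so its level and those of mt-Co3 and mt-Atp6 are uncertain. These pseudogenes were listed at 32824 ± 726 TPM (Gm28661, chromosome 1, 24614885 to 24615565), 16142 ± 1216 TPM (Gm29216), 14726 ± 1742 TPM (Gm10925) and 12318 ± 1197 TPM (Gm28437), and were chosen after their values were seen. With them, the mitochondrial share of TPM was 41.5% ± 1.81.

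Genes of the contractile apparatus of the cardiomyocyte were among the most abundant nuclear mRNAs. Myl2, the ventricular regulatory myosin light chain (chromosome 5, 122100951 to 122113472), had 8743 ± 246 TPM, and Myh6, the alpha cardiac myosin heavy chain (chromosome 14, 54941921 to 54966927), had 8570 ± 33.4 TPM. Leaving out the haemoglobins, next came Mb, the muscle oxygen store myoglobin, with 7675 TPM, Atp2a2, the calcium pump of the sarcoplasmic reticulum, with 5269 ± 495 TPM, and Actc1, cardiac actin, with 5000 ± 221 TPM. Tnni3 had 4153 ± 173 TPM, Myl3 4061 ± 221 TPM, Tpm1 3889 ± 163 TPM and Tnnt2 3686 ± 50.01 TPM. All 26 members of the sarcomere list were at 1 TPM or more in both libraries, with a median of 673 ± 67.5 TPM and a range from 62.0 to 8743 TPM. Of the 25 most abundant nuclear protein-coding genes, 7 were more than 1.5 times higher in the kallisto-layout table, Myl2 with 18468 TPM, Hba-a1 with 10777, Hbb-bs with 10386 (these 2 above Mb with 9238 and Myh6 with 7370), Tnnt2 with 6655, Tnni3 with 6270, Gapdh with 3738 and Cryab with 2145, and Cox6b1 was lower by over 1.5 times with 1021.

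Haemoglobin mRNAs from blood stood among the same top genes but were the least even. Hbb-bs had 8658 TPM in replicate 1 and 4142 TPM in replicate 2, Hba-a1 7305 and 3377 TPM, and Hba-a2 6317 and 3148 TPM. The rest of the 25 most abundant nuclear protein-coding genes were Atp5b with 3343 TPM, Pln with 2786 TPM, Fabp3 with 2317 TPM, Tnnc1 with 2288 TPM, Slc25a4 with 1876 TPM, Cox4i1 with 1839 TPM, Cox6b1 with 1779 TPM, Gapdh with 1758 TPM, Lpl with 1663 TPM, Atp5a1 with 1660 TPM, Aldoa with 1572 TPM, Ckm with 1504 TPM and Cryab with 1358 TPM.

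The 43 nuclear genes of oxidative phosphorylation had a median of 637 ± 20.5 TPM, close to that of the sarcomere list, and all were at 1 TPM or more in both libraries. In the kallisto-layout table their median was 955 TPM, above the 805 TPM of the sarcomere list. The 26 genes of fatty acid oxidation had a median of 343 ± 57.9 TPM, led by Fabp3, which carries fatty acids in the cytosol, and Lpl, which frees them from lipoproteins, followed by Hadhb with 863 TPM in replicate 1 and 986 TPM in replicate 2. The tricarboxylic acid cycle list had a median of 315 ± 1.27 TPM and the glycolysis list 217 ± 6.60 TPM. Ketone metabolism had a median of 120 TPM over 5 genes, led by Oxct1, which activates ketone bodies for oxidation. Calcium handling genes had a median of 115 ± 1.79 TPM, among them Ryr2, the calcium release channel, with 396 ± 5.27 TPM.

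Cardiac transcription factors, ion channels and gap junctions had far lower medians than the contractile genes. The list of cardiac transcription factors had a median of 27.6 ± 0.463 TPM, led by Esrra, Mef2a, Mef2d and Gata4, and Hand1 was at 0 TPM in both libraries. Ion channels and gap junctions had a median of 11.2 ± 3.65 TPM, led by Gja1, the main ventricular connexin, with 176 ± 24.2 TPM. Cardiac splicing factors had a median of 40.6 TPM, heat shock genes 130 TPM and antioxidant genes 115 ± 8.31 TPM. In the hypertrophy and stress list, Myh7, the beta cardiac myosin heavy chain, led with 890 ± 25.6 TPM, and Fgf21 was at 0 in both libraries. The list of senescence and age-related secretion had a median of 0.52 TPM, led by Cdkn1a, a cell cycle inhibitor, with 32.4 TPM in replicate 1 and 57.9 TPM in replicate 2.

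Markers of endothelial cells, fibroblasts, mural cells, macrophages and mesothelium were present at lower levels. Whether these transcripts came only from the heart was not tested. Endothelial markers had a median of 33.7 TPM with Aqp1, Ly6c1, Eng and Vwf highest, fibroblast markers 18.7 TPM with Gsn and Mgp highest, and mural cell markers 9.19 TPM with Rgs5 highest. Macrophage markers had a median of 3.26 TPM in replicate 1 and 6.63 TPM in replicate 2, and mesothelial markers 1.65 and 2.63 TPM. Skeletal muscle markers, at a median of 0.185 TPM, included Myh2, Myh4 and Myog at 0 in both libraries. Of the liver markers, Trf, the iron carrier transferrin, had 16.5 TPM in replicate 1 and 26.1 TPM in replicate 2, while Alb, Serpina1c and Fgb were at 0 in both libraries, and the Schwann and neuronal markers Th and Chga were among those at 0 as well. These are levels in bulk tissue and not shares of cells.

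In most paralog pairs the form known from adult cardiac muscle exceeded its relative. Of 30 pairs, 27 were called, all with the first-named gene higher, and 17 exceeded 10-fold. Myh6 exceeded Myh7, its slow relative, by 3.27 ± 0.036 on the log2 scale, or 9.63-fold. Actc1 exceeded the skeletal actin Acta1 by 4.96 ± 0.084 and Tnnt2 exceeded the slow skeletal Tnnt1 by 8.79, or 8.64 with a pseudocount of 1. Atp2a2 exceeded the fast skeletal pump Atp2a1 by 13.47, or 11.91 with a pseudocount of 1, since Atp2a1 was near the floor at 0.365 TPM. Tnni3 exceeded Tnni1, the form of the developing heart, by 13.38 in replicate 1 and 12.34 in replicate 2, with a mean of 12.86, or 11.46 with a pseudocount of 1, since Tnni1 was under 1 TPM in both.

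Most metabolic pairs were called as well. Cpt1b, the muscle carnitine palmitoyltransferase, exceeded Cpt1a by 3.61 ± 0.21, Slc2a4, the insulin-responsive glucose transporter, exceeded Slc2a1 by 5.18 ± 0.26, and Ckm exceeded Ckb by 5.85 ± 0.097. Ldhb exceeded Ldha by 2.10 ± 0.087 and Cox6a2 exceeded Cox6a1 by 3.53 ± 0.33. The pairs Pdk4 and Pdk2, Nppa and Nppb, and Rbm20 and Rbm24 were not called. Their log2 ratios were -0.31 in replicate 1 and 1.46 in replicate 2 for Pdk4 over Pdk2, 0.11 and 3.001 for Nppa over Nppb, and 0.20 and -0.075 for Rbm20 over Rbm24.

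The ratio of Myh6 over Myh7 was 2.10 on the log2 scale in the kallisto-layout table, and 32.3% of the 31-nt words of Myh6 also occur in Myh7. Cox7a1 over Cox7a2 was 1.42 ± 0.042 and 0.78 in the kallisto-layout table, while Myl2 over Myl7 was 6.49 and 5.12 (mean 5.80, and 6.58 in the kallisto-layout table), Myl3 over Myl4 5.40 and 3.93, and Acacb over Acaca 3.33 and 1.75 in replicates 1 and 2.

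**Figure D2:**
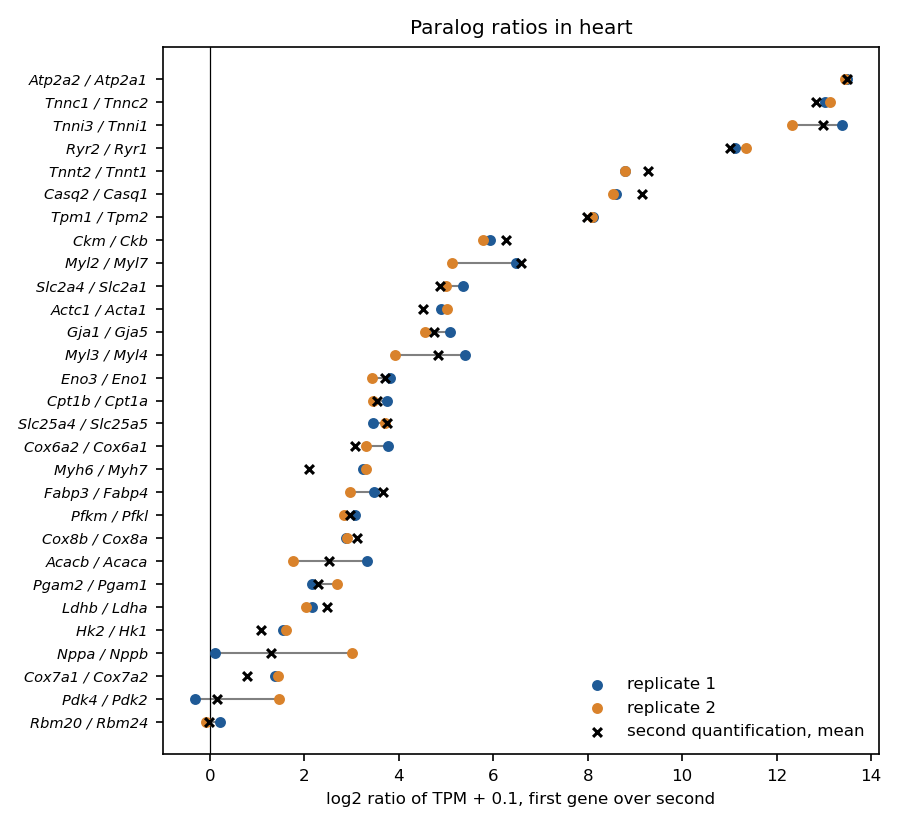
Log2 ratio of TPM + 0.1 for pairs of paralogs, first-named gene over second, with 1 point per library and a cross for the mean of the kallisto-layout table. Myh6 over Myh7 lay at 3.24 and 3.29 in the libraries and at 2.10 in the kallisto-layout table.

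Several cardiac genes were read mainly from 1 annotated transcript. Tpm1-205 took 96.9% ± 0.228 of the TPM of Tpm1, Slc25a3-206 took 92.3% ± 0.273 of Slc25a3, the mitochondrial phosphate carrier, and Ryr2-201 took 85.0% ± 0.739 of Ryr2. Atp2a2-202 took 77.3% ± 0.516 of Atp2a2 and Ldb3-203 took 68.3% ± 1.77 of Ldb3, a Z-disc protein. The giant sarcomere spring titin was split, with 34.6% ± 0.519 for Ttn-201 (81843 nt) and 28.7% ± 0.312 for Ttn-215. Over the 20 genes, the median share of the top transcript was 54.1%, and the top transcript was the same in both libraries for 18 genes.

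Transcript shares depended on the table more than on the library. The top transcript was the same in both tables for 14 of 20 genes, and 6 of the 20 had a share over 50% in both. Tnnt2-211 took 66.2% ± 0.205 of Tnnt2 in the RSEM-layout table, while in the kallisto-layout table its share was close to 0 and Tnnt2-209 led with 34.3%. Tpm1-205 took 72.0% and Ldb3-203 took 68.3% in the kallisto-layout table.

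Across genes the 2 libraries were close, with some genes far apart. Over 12510 genes with a mean TPM of 1 or more, Pearson's r of log2(TPM + 0.1) was 0.951 and Spearman's rho 0.967, and the SD of the log2 ratio was 0.64. These are correlations across genes, which are not independent replicates. Against counting noise alone the chi-square was 31.4 per degree of freedom. The biological coefficient of variation was 0.178 ± 0.0035 (bootstrap SD over 15007 genes). Between the libraries 528 genes (4.22%) were 2-fold or more apart, 413 higher in replicate 2 and 115 lower. At 100 TPM or more, 10 of 580 protein-coding genes were 2-fold or more apart.

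The 10 genes highest in replicate 2 over replicate 1 included secreted proteins known from the airway and enzymes known from fat. Bpifa1, a secreted protein of the upper airway (chromosome 2, 154142880 to 154149219), had 0 counts in replicate 1 and 4650 in replicate 2. With replicate 1 set at the floor of 3 counts it was 1507-fold higher, and the exact 95% interval started at 1225-fold. By the same floor Glycam1, a mucin of lymph node vessels, was 235-fold higher (interval from 191). Reg3g, an antibacterial lectin of mucosal surfaces, was 129-fold higher (from 104). The secretoglobins Scgb1a1 and Scgb3a2 were 112-fold higher each (from 91.0 and 90.4). Scgb3a1 was 113-fold higher in counts (95% interval 48.2 to 350) and Cyp2f2, an enzyme of airway club cells, 36.2-fold (24.4 to 56.2). Pck1, an enzyme of glycerol and glucose synthesis, was 17.9-fold higher (15.4 to 20.9), the fatty acid synthase Fasn 15.9-fold (15.0 to 16.7), and Ucp1, the uncoupling protein of brown fat, 12.2-fold (10.3 to 14.5).

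The genes lowest in replicate 2 differed less. Rrad, a small GTP-binding protein that restrains calcium channels, was 3.13-fold higher in counts in replicate 1 than in replicate 2 (2.95 to 3.33), Nppb, the B-type natriuretic peptide, 3.12-fold (2.93 to 3.32) and Manf, an endoplasmic reticulum stress factor, 2.96-fold (2.73 to 3.21). G0s2 was 2.70-fold higher, Tent5c 2.52-fold, Sdf2l1 2.44-fold and Hbb-bt 2.29-fold. Mrpl23 was 2.83-fold higher (2.19 to 3.68), but its TPM in the kallisto-layout table was 62.0 in replicate 1 and 63.4 in replicate 2. Of 7479 protein-coding genes with a mean TPM of 5 or more and a mean count of 100 or more, 31 were 4-fold or more higher in replicate 2 and 0 were 4-fold or more lower. With 1 library on each side these differences have no replicate check, and the intervals cover counting error only.

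**Figure D3:**
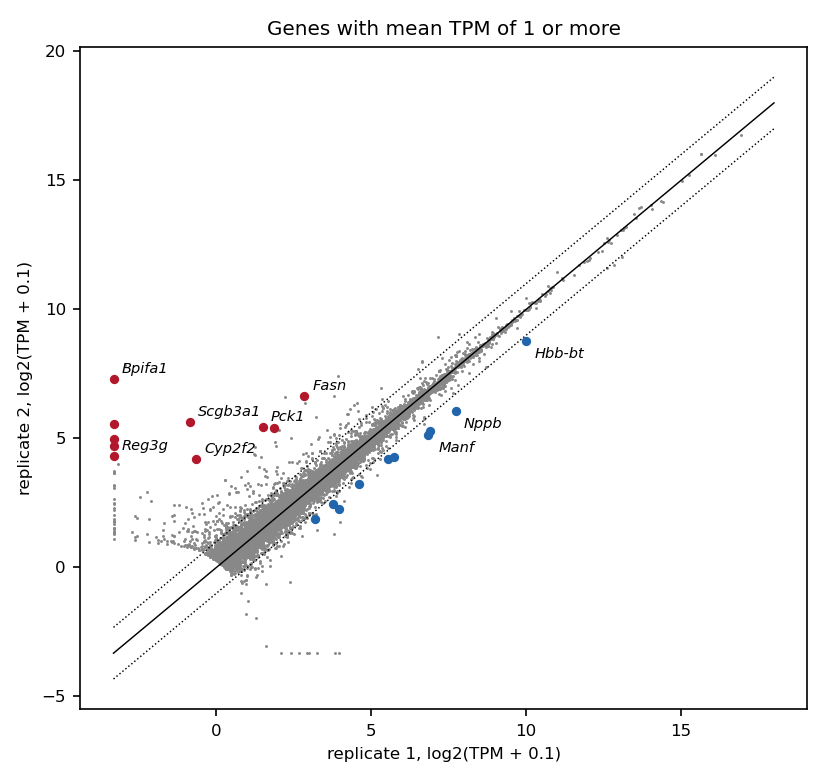
Log2(TPM + 0.1) of replicate 2 against replicate 1 for genes with a mean TPM of 1 or more, with a solid line of equality and dotted lines at a 2-fold difference. Red and blue points are the 10 genes highest and lowest in replicate 2 over replicate 1, and Bpifa1 lies at 0 TPM in replicate 1 and 157 TPM in replicate 2.

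By gene lists, replicate 2 was higher in markers of fat, lymphocytes and atrium, and replicate 1 in markers of blood and in genes of the unfolded protein response. Of 42 lists, 11 had a median log2 ratio in the upper 2.5% of matched random lists and 8 in the lower 2.5%. Chance would give 2.1 in all if the genes of a list varied independently. Genes of a cell type or process may move together, which the random lists do not allow for. All 11 adipocyte markers were higher in replicate 2, with a median log2 ratio of 3.11, led by Cfd, Plin4, Car3 and Cidea. The median was 2.48 for T cell markers, 11 of 11 higher but 0 at 1 TPM or more in both libraries (1.18 with a pseudocount of 1), and 2.44 for B and plasma cell markers, 11 of 11 higher, with Igkc at 4.55 TPM in replicate 1 and 97.7 TPM in replicate 2. Atrial markers had a median of 0.73, 10 of 12 higher, with Nppa at 228 and 531 TPM, Myl4 at 99.5 and 257 TPM, Myl7 at 99.4 and 246 TPM and Sln at 14.4 and 31.8 TPM. In the lung and airway list the median was 1.31, but 0.22 with a pseudocount of 1 and 0.18, no longer above the bound, with posterior mean TPM. In this list Scgb1a1 had 31.3 TPM in replicate 2, while the alveolar marker Sftpc was at 0 TPM in both libraries.

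The other medians above the bound were those of thymus markers with 1.25 (0.30 with a pseudocount of 1, and 0.32 and no longer above the bound in the kallisto-layout table), interferon response with 0.49, circadian clock genes with 0.27, fibroblast markers with 0.25, fatty acid oxidation genes with 0.12 and antioxidant genes with 0.076. Erythroid markers were below the bound with a median of -1.12, 0 of 8 higher in replicate 2, and neutrophil markers with -1.77, all under 3 TPM, a ratio that was -0.37 with a pseudocount of 1 and -0.051, no longer below the bound, with posterior mean TPM. The unfolded protein response list had a median of -0.48, with Hspa5, the main chaperone of the endoplasmic reticulum, at 421 TPM in replicate 1 and 219 TPM in replicate 2, Hsp90b1 at 192 and 124 TPM, and Calr at 165 and 116 TPM. Cardiac transcription factors had a median of -0.25, ventricular markers -0.20, lymphatic endothelial markers -0.20, and hypertrophy and stress genes -0.10.

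The sarcomere list had a median log2 ratio of -0.058 with 5 of 26 genes higher in replicate 2, although its median TPM was 625 in replicate 1 and 720 in replicate 2, and its ratio was 0.027 in the kallisto-layout table. The calls of 12 of the 19 lists held in all 5 alternatives, those of adipocyte, T cell, B and plasma cell, atrial, fibroblast, erythroid and ventricular markers, of fatty acid oxidation, interferon response, circadian clock and unfolded protein response genes, and of cardiac transcription factors.

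**Figure D4:**
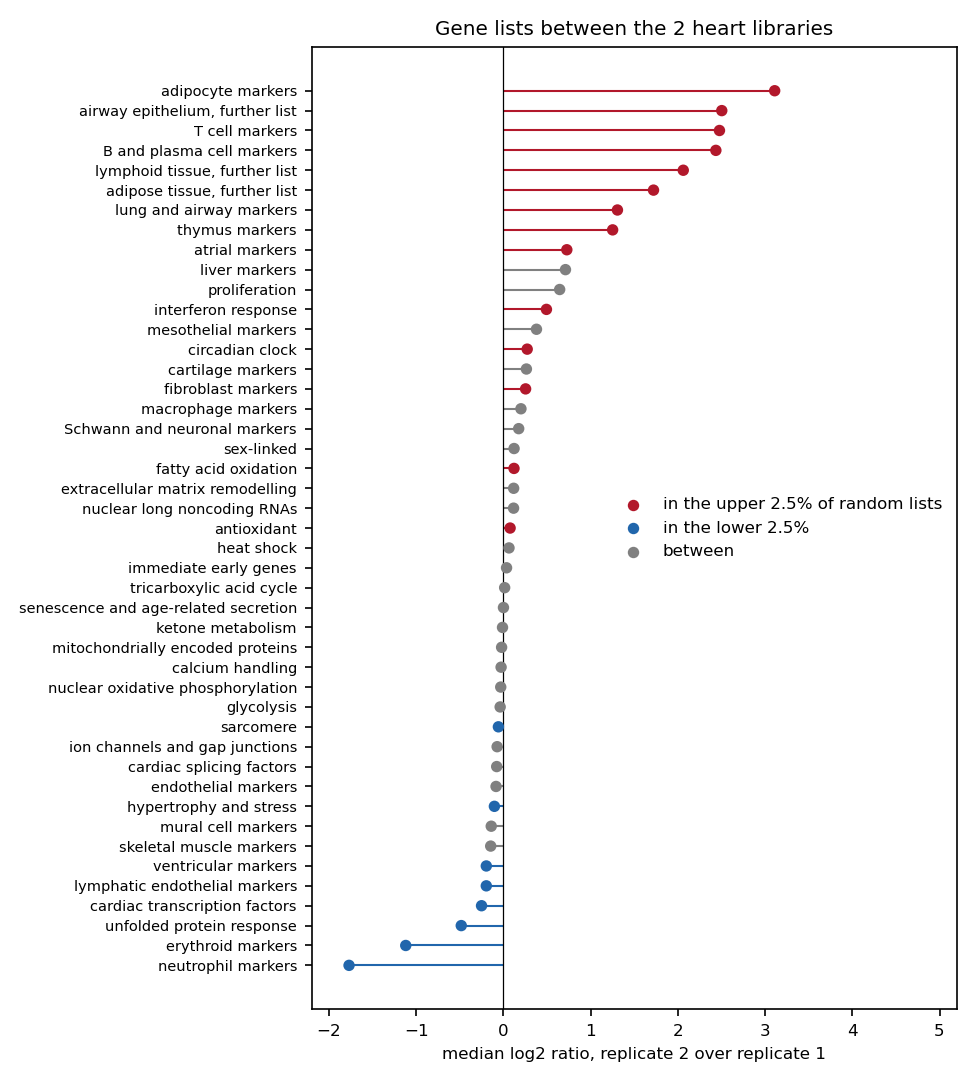
Median log2 ratio of replicate 2 over replicate 1 for 42 gene lists and 3 further lists of airway, adipose and lymphoid genes chosen later. Red and blue mark medians in the upper and lower 2.5% of matched random lists, with adipocyte markers at 3.11 and erythroid markers at -1.12.

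The remaining 23 lists lay between the bounds. Those above 0 were liver markers with 0.71, proliferation with 0.64, mesothelial markers with 0.38, cartilage markers with 0.26, macrophage markers with 0.20, Schwann and neuronal markers with 0.17, sex-linked genes with 0.12, extracellular matrix remodelling with 0.12, nuclear long noncoding RNAs with 0.12, heat shock with 0.063, immediate early genes with 0.035 and the tricarboxylic acid cycle with 0.014. The median was 0 for senescence and age-related secretion. Those below 0 were ketone metabolism with -0.011, mitochondrially encoded proteins with -0.021, calcium handling with -0.027, nuclear oxidative phosphorylation with -0.031, glycolysis with -0.038, ion channels and gap junctions with -0.073, cardiac splicing factors with -0.078, endothelial markers with -0.085, mural cell markers with -0.14 and skeletal muscle markers with -0.15. The median TPM was higher in replicate 2 for mitochondrially encoded proteins, calcium handling, glycolysis, endothelial markers and skeletal muscle markers, and lower for extracellular matrix remodelling, immediate early genes, circadian clock genes and nuclear long noncoding RNAs, the opposite sign of their log2 ratios. In the kallisto-layout table the log2 ratios of ketone metabolism, mitochondrially encoded proteins, calcium handling, nuclear oxidative phosphorylation, glycolysis, ion channels and gap junctions, and cardiac splicing factors were above 0, and with TMM-scaled counts those of the tricarboxylic acid cycle, Schwann and neuronal markers and immediate early genes were below 0, as was that of sex-linked genes with posterior mean TPM. Proliferation moved above the bound with a pseudocount of 1 (0.21), TMM-scaled counts (0.79) and posterior mean TPM (0.39), mesothelial markers in the kallisto-layout table (0.61) and liver markers with a pseudocount of 1 (0.32). Mural cell markers moved below the bound with a pseudocount of 1 (-0.13) and TMM-scaled counts (-0.16), and skeletal muscle markers with TMM-scaled counts (-0.20) and in the kallisto-layout table (-0.18).

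Sex-linked transcripts and spike-ins matched the labels. Xist, the RNA of the inactive X chromosome, had 17.0 TPM in replicate 1 and 18.3 TPM in replicate 2. The Y-linked genes Kdm5d and Eif2s3y were at 0 in both libraries, and Ddx3y and Uty did not exceed 0.01 TPM. ERCC spike-ins took 0.492% of expected counts in replicate 1 (exact 95% interval 0.490 to 0.494) and 0.515% in replicate 2 (0.513 to 0.518), with 67 and 69 of 96 detected. Over 41 spike-ins with more than 10 counts, Pearson's r of the log2 values was 0.998 and the median log2 ratio 0.020.

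Genes furthest apart between the 2 quantifications of the same reads included short noncoding RNAs, pseudogenes, mt-Atp8 and the nuclear protein-coding gene Gm34302. Rn7s1 and Rn7s2, the 7SL genes on chromosome 12, had 58807 TPM each in the RSEM-layout table and 1.17 TPM in the kallisto-layout table. mt-Atp8 had 5952 TPM and 0, Gm12338 had 1517 TPM and 0, Gm24265 had 444 TPM and 0, and Gm34302 had 421 TPM and 0, while Gm28439 had 0 and 962 TPM. Both genes annotated as Rmrp were at 0 in the kallisto-layout table, against 859 and 778 TPM. Across 12504 genes, Pearson's r between the tables was 0.821 in replicate 1 and 0.800 in replicate 2, and 753 and 809 genes were 2-fold or more apart.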

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

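The alternatives were chosen before the data were examined, except that counting the 4 pseudogenes as mitochondrial was chosen after the data were seen. No paired analysis was possible because there is 1 group. Detected genes numbered 7605 at 5 TPM, 16931 at 0.1 TPM, 15503 with posterior means, and 12307 to 12634 with either library alone. The mitochondrial share of TPM was 29.6% by expected counts, 38.04% in the kallisto-layout table and 41.5% with the 4 pseudogenes (32.6% to 35.3% with either library alone). The ERCC share was 0.818% by TPM and 0.392% in the kallisto-layout table (0.492% to 0.515%). The sarcomere median was 805 TPM in the kallisto-layout table and 1657 when TPM was rescaled over nuclear protein-coding genes (625 to 720). Myh6 over Myh7 was 2.10 in the kallisto-layout table (3.24 to 3.29), and the median top transcript share 38.1% there and 53.6% with posterior means (53.9% to 54.4%). With a mean of 2 libraries, either alone lies within 1 SD by arithmetic, so these ranges are no check.

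Pearson's r was 0.974 with a pseudocount of 1, 0.972 with no filter, 0.976 with posterior means and 0.968 over protein-coding genes. Genes 2-fold or more apart numbered 325 with a pseudocount of 1, 2768 with no filter and 162 at 5 TPM, and the biological coefficient of variation was 0.223 with no filter and 0.145 at 100 or more counts. The share of these genes higher in replicate 2 was 78.2%, and 76.0% to 83.3% under 4 other scalings or tables. Adipocyte markers stayed in the upper 2.5% in all alternatives, at 2.76 to 3.08. Signs of paralog ratios and called lists reversed for Pdk4 over Pdk2 (-0.31 without replicate 2, 1.46 without replicate 1), Rbm20 over Rbm24 (-0.032 in the kallisto-layout table, -0.075 without replicate 1, 0.20 without replicate 2) and the sarcomere ratio (0.027 in the kallisto-layout table), for which the cause was not tested. Of 110 ratios of the 22 called lists (the 3 further lists included) under 5 alternatives, 100 kept the call, 9 lost it and 1, of the sarcomere, changed sign; of 115 ratios of lists not called, 9 gained a call. Of the lists not called, 11 changed sign in at least 1 alternative, 7 of them in the kallisto-layout table. Over genes with a mean TPM of 1 or more, the median log2 ratio was 0.023, and 0.090 in the kallisto-layout table. The sarcomere ratio of 0.027 there was thus still below the median of all genes. Depth limits neutrophil, thymus, T cell and airway markers, near the floor in 1 library or both.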

Other observations

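The tests chosen only after the result was seen were those of Sftpc, of a scale factor shared by all genes, of short transcripts without counts and of effective length as the whole cause, and the 3 further lists were chosen after the data were first seen but before the values of their genes were.

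Several transcripts of red blood cells differed between the libraries by a similar factor. Of the 8 erythroid markers, 7 were 2-fold or more lower in replicate 2. Alas2, the erythroid enzyme of haem synthesis, chosen after its values were seen, had 105 TPM in replicate 1 and 47.5 TPM in replicate 2, a log2 ratio of -1.14, beside -1.06 for Hbb-bs and -1.11 for Hba-a1. The natriuretic peptides went opposite ways, with Nppa at a log2 ratio of 1.22 and Nppb at -1.68. Among cardiac transcription factors Gata4 had 55.9 TPM in replicate 1 and 33.5 TPM in replicate 2, and Prox1 in the lymphatic list 28.7 and 14.2 TPM.

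Genes of fat, airway and lymphoid tissue were higher in replicate 2. The median log2 ratio of all genes with a mean TPM of 1 or more was 0.023 (bootstrap 95% interval 0.018 to 0.029). Of the lists of these tissues, thymus markers were lowest with 1.25 (0.30 with a pseudocount of 1). The difference was thus not shared by all genes. This could hardly have come out otherwise, since that list had been called against random lists of the same libraries. It is therefore no separate test of a scale factor shared by all genes. The lowest median of the adipocyte list over TPM, TMM and spike-in scaling, 2.999, decides nothing either, since these scalings moved the median of all genes by at most 0.028. For lung alveolar tissue, or reads of a lung library, as the source, only Sftpc was examined. Its credibility interval in replicate 2 ended at 0.247 TPM against 31.3 TPM for Scgb1a1. This shows no sign of the alveolar marker, but it rests on 1 gene whose value had been seen before the test was chosen. It does not decide on this source. Adipose, airway and lymphoid tissue around the heart, or reads of libraries of these tissues, may be the source: all 3 of the further lists lay in the upper 2.5% of matched random lists, with median log2 ratios of 2.503 for airway genes (16 of 16 higher, Ltf highest at 0.06 and 3.83 TPM, 0 of 17 at 1 TPM in both libraries), 1.72 for adipose genes (16 of 16 higher, 11 at 1 TPM in both) and 2.06 for lymphoid genes (16 of 16 higher, 3 at 1 TPM in both). With a pseudocount of 1 these medians were 0.60 for airway, 1.02 for adipose and 1.32 for lymphoid genes, still in the upper 2.5%. Tissue taken along at dissection and reads from other libraries were not separated, and no biological explanation was tested, since the design has 1 group.

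Gene TPM differed between the 2 quantifications. Effective length acting on TPM alone, with counts left as they are, is argued against as the whole cause. The median absolute log2 count ratio of the 762 genes 2-fold or more apart in mean TPM was 3.46 (bootstrap 95% interval 3.10 to 3.74). An effect of effective length on how reads were split among genes was not tested. Reads given to different genes may account for part of the difference, as 76.2% of these 762 genes were also 2-fold or more apart in counts. This share does not separate reads moved to another gene from reads left out. Reads on transcripts shorter than the fragment length may have been left out of the kallisto-layout table, since 96.9% of 262 single-transcript genes under 325 nt had no count there, against 0% of 593 genes of 2000 nt or more. A partial effect of effective length stays open, with counts moved as well: the median log2 TPM ratio, kallisto-layout over RSEM-layout, of genes under 500 nt minus that of genes of 2000 nt or more was -5.04, opposite in sign to the prediction, but from 325 to 500 nt the TPM ratio was -1.36 where the count ratio was -2.57; no biological explanation applies to 2 quantifications of the same reads.

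The 4 pseudogenes of mitochondrial sequence on chromosome 1 stood among the most abundant genes. Sequence shared with the mitochondrial genome may account for their counts, since 99.5% of their 31-nt words occur in mitochondrial transcripts, with Gm28661 matching mt-Co2, Gm29216 mt-Co1, Gm10925 mt-Atp6 and Gm28437 mt-Co3. Transcription of the nuclear copies stays open, since their summed TPM in the kallisto-layout table was 0.949 times that in the RSEM-layout table, while single members moved far apart (Gm10925 from 14726 to 0.0915 TPM, Gm29216 from 16142 to 6020, Gm28437 from 12318 to 25933), and both tables face the same shared sequence.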
